A study of Homo sapiens with 4 samples.

How the data were processed

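Total RNA was measured in 4 samples of primary human microvascular endothelial cells, 2 on a flat and 2 on a channelled silicone surface. Per the labels' protocols, the cells were lysed with Trizol, the RNA was purified on RNeasy columns and biotin-labelled, and the surfaces were plasma treated and coated with collagen I before seeding. The groups and replicate numbers were taken from the sample titles; for one micropatterned sample the title and the source name give different replicate numbers, and the title was used.

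The data are one table of signal values deposited by the authors, with 32321 probe sets and 4 columns. The deposited values are on a log2 scale, as their range shows (2.32 to 13.8). The only tool named per the submitters' processing notes is MAS5, with no role and no version; the background correction, the summary over probes and any normalization are not given in the sources used here. No scanner files were used here. No genome build is named, so no coordinates are given.

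Probe sets were named through the platform annotation: 19158 had 1 gene symbol, 1388 had several and 11775 had none listed. Symbols were brought up to date through the gene number in a RefSeq table of assembly GRCh38.p14, in which 19128 of the 1-symbol probe sets matched; the other 30 kept the platform symbol. Probe sets with several symbols or none were left out of the gene test. For a gene with several probe sets, the one with the highest mean over the 4 arrays was used, which left 18404 genes. Genes whose mean lay at or below the 30th percentile of all probe sets (log2 5.35) were left out as dim, 3339 genes, and 15065 were tested. The column medians spanned 0.113, above the tolerance of 0.1 fixed before the data were examined, so the 4 columns were quantile normalized. Quantile normalization gives every array the same distribution, so a true shift of most genes in one direction would be removed.

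The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default prior, no covariates), as micropatterned minus control. Benjamini-Hochberg adjustment ran over the 15065 genes, with a threshold of 0.05. The prior carried 5.33 degrees of freedom. Median standard deviations were 0.0758 within the control pair and 0.0572 within the micropatterned pair. A second, descriptive count took genes at an unadjusted p under 0.01 with at least a 1.5-fold change whose arrays did not overlap.

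The 45 gene lists were fixed before the data were examined and tested with camera (competitive, two-sided, preset correlation 0.01) where at least 5 members were tested, with adjustment over the 45 lists. Camera with an estimated correlation and fry were run beside it. Lists written as symbol prefixes took all current symbols with that prefix, histone prefixes were matched through older symbols, ribosomal protein prefixes left out kinases and pseudogenes, and the oxidative phosphorylation list includes assembly factors. Named genes follow a rule fixed beforehand: up to 12 genes in each direction with the largest change among those that passed with no overlap of arrays, and in each list up to 4 members with the smallest p. Values of further genes were not chosen by this rule where the text says so.

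Alternatives were: values as deposited, median centring, no filter or a filter at the 50th percentile, the mean over a gene's probe sets, a trended and robust prior, a replicate block, each array left out, no shared prior, an adjusted p threshold of 0.1 and an estimated correlation. When an array is left out, the lone array of its group is assumed to vary like the other group. Cyclic loess and a filter at the 75th percentile were added after the data were examined, as were 9 gene families defined by symbol.

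The pipeline was tested on simulated data: 20 simulated sets of the comparison over 15065 genes, each with 100 genes changed per fold size. It recovered 61.8% of 1.5-fold and 98.0% of 2-fold changes, with 5.02% of calls false. It called a list shifted by 0.2 log2 in 20 of 20 sets, and smaller shifts of lists were not simulated. The simulated genes varied independently, with a spread drawn from limma's fitted prior and no effect shared across an array. These rates therefore hold only for independent genes and do not measure false calls on the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A check of base composition was not possible, since no genome was used here.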

Results

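RNA from primary human microvascular endothelial cells, which line the smallest blood vessels, was measured on 4 single-colour whole-transcript arrays. The cells had been grown on a silicone elastomer, polydimethylsiloxane, coated with collagen I. The surfaces compared were flat and channelled: 2 arrays came from cells on a flat surface (control) and 2 from cells on parallel channels 30 µm wide and 30 µm apart (micropatterned). The comparison asks how the shape of the surface alters gene expression in these cells. The deposited log2 signals had medians of 6.73 and 6.72 on the control arrays and 6.62 on both micropatterned arrays. Signals of the control arrays correlated at r = 0.995 across probe sets and those of the micropatterned arrays at r = 0.994, and the 4 pairs between groups at 0.984 to 0.992. The median absolute difference was 0.107 between the control arrays and 0.0808 between the micropatterned arrays; between groups it ran from 0.121, for control replicate 2 and micropatterned replicate 2, to 0.173. Probe sets are not independent replicates. The first principal component held 71.6% of the variance and separated the groups, with scores of -18.1 and -10.8 for control replicates 1 and 2 and 18.3 and 10.6 for micropatterned replicates 1 and 2. With 2 arrays per group, the number of arrays limits the precision, and an exact two-sided permutation test of a single value cannot give a p below 0.333. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical.

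On the channels, small non-coding RNAs led the genes that were higher and genes of several unrelated kinds led those that were lower. The small nucleolar RNA SNORD58A (probe set 8023259) rose by 1.29 ± 0.21 on the log2 scale (n = 2 per group, limma adjusted p = 0.0281), SNORD113-4 by 1.27, SNORA20 by 1.12 and SNORD38B by 1.06. Each ± in the text is limma's moderated standard error. It draws on the spread of all genes through the prior, not on that gene's arrays alone. For SNORD58A the standard deviation was 0.54 in the control pair and 0.013 in the micropatterned pair. The vault RNA VTRNA1-2 rose by 1.09, the spliceosomal RNA RNU5B-1 by 1.03 and the microRNA precursor MIR186 by 0.94. Among protein-coding genes, CCDC102B rose by 1.07 and DSCC1, a factor that helps load the replication clamp, by 0.99. The zinc finger genes ZNF615 and ZNF681 rose by 1.00 and 0.94, and the potassium channel subunit KCNMB3 by 0.93. Control means of SNORD113-4, VTRNA1-2, RNU5B-1, ZNF681 and MIR186 ran from 4.87 to 5.15, below the dim filter's log2 5.35. The largest decreases were in ZBTB22 (probe set 8125731; -1.21 ± 0.11, adjusted p = 0.0246), TMEM242 (-1.04), TEX52 (-0.97) and REXO1L1P (-0.94). They were followed by the germ cell RNA-binding protein DND1 (-0.92), the collagen receptor LAIR2 (-0.86), the axon guidance factor DRAXIN (-0.82) and LCN10 (-0.80). The other genes among the 12 largest decreases belong to hair and epidermis, namely KRTAP10-4 (-0.82), KRTAP10-3 (-0.80), LCE1D (-0.80) and SPRR4 (-0.80). The KRTAP10 genes are near-identical copies and their separate values are uncertain. Further probe sets of some genes disagreed in size or sign: TMEM242 was 0.30 higher in its other probe set, ZBTB22 -0.17, and KCNMB3 0.29, 0.17 and 0.10 in its others.

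Of 15065 genes tested with limma, 1542 passed an adjusted p of 0.05, 698 higher and 844 lower on the channels. Their median absolute log2 fold change was 0.46, or 1.38-fold. At least 1.5-fold changes numbered 256, of which 154 were higher and 102 lower, and 10 genes reached 2-fold. The arrays of the groups did not overlap in 58.9% of genes, where a single gene would do so with a chance of 33.3%. An effect shared across an array would move many genes together, so 33.3% is not a chance level for the share. At an unadjusted p under 0.05 there were 4465 of the 15065 genes, 2011 higher and 2454 lower. The counts of list members at that p are to be read against this number. At an unadjusted p under 0.01, 273 genes had at least a 1.5-fold change with no overlap, 170 higher and 103 lower. That number was 548 without control replicate 2 and 620 without micropatterned replicate 2. The number of calls changed with single arrays: without control replicate 1 limma called 0 genes (3698 at an unadjusted p under 0.05; smallest adjusted p 0.0840), and this holds for every gene call named in the text. Without micropatterned replicate 1 it called 8, 7 higher and 1 lower, without control replicate 2 it called 1112, 700 higher and 412 lower, and without micropatterned replicate 2 it called 1389. Leaving out an array also removes a residual degree of freedom, and the tables do not separate that loss from the array's own values. The balance of directions depended on scaling: 54.7% of calls were lower after quantile normalization, 61.4% of 3094 with the values as deposited, 44.6% of 1354 after cyclic loess and 25.7% of 4308 when each array was centred on its median. Median centring put the median log2 fold change of all tested genes at 0.15, against 0.00 after quantile normalization, and values under it are to be read relative to that shift. Calls were concentrated among genes of low and middle signal: 72 of 5583 genes above the 75th percentile of signal were called, 1.29%, against 15.7% of 5724 genes from the 50th to the 75th percentile and 15.1% of 3758 from the 30th to the 50th.

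**Figure D1:**
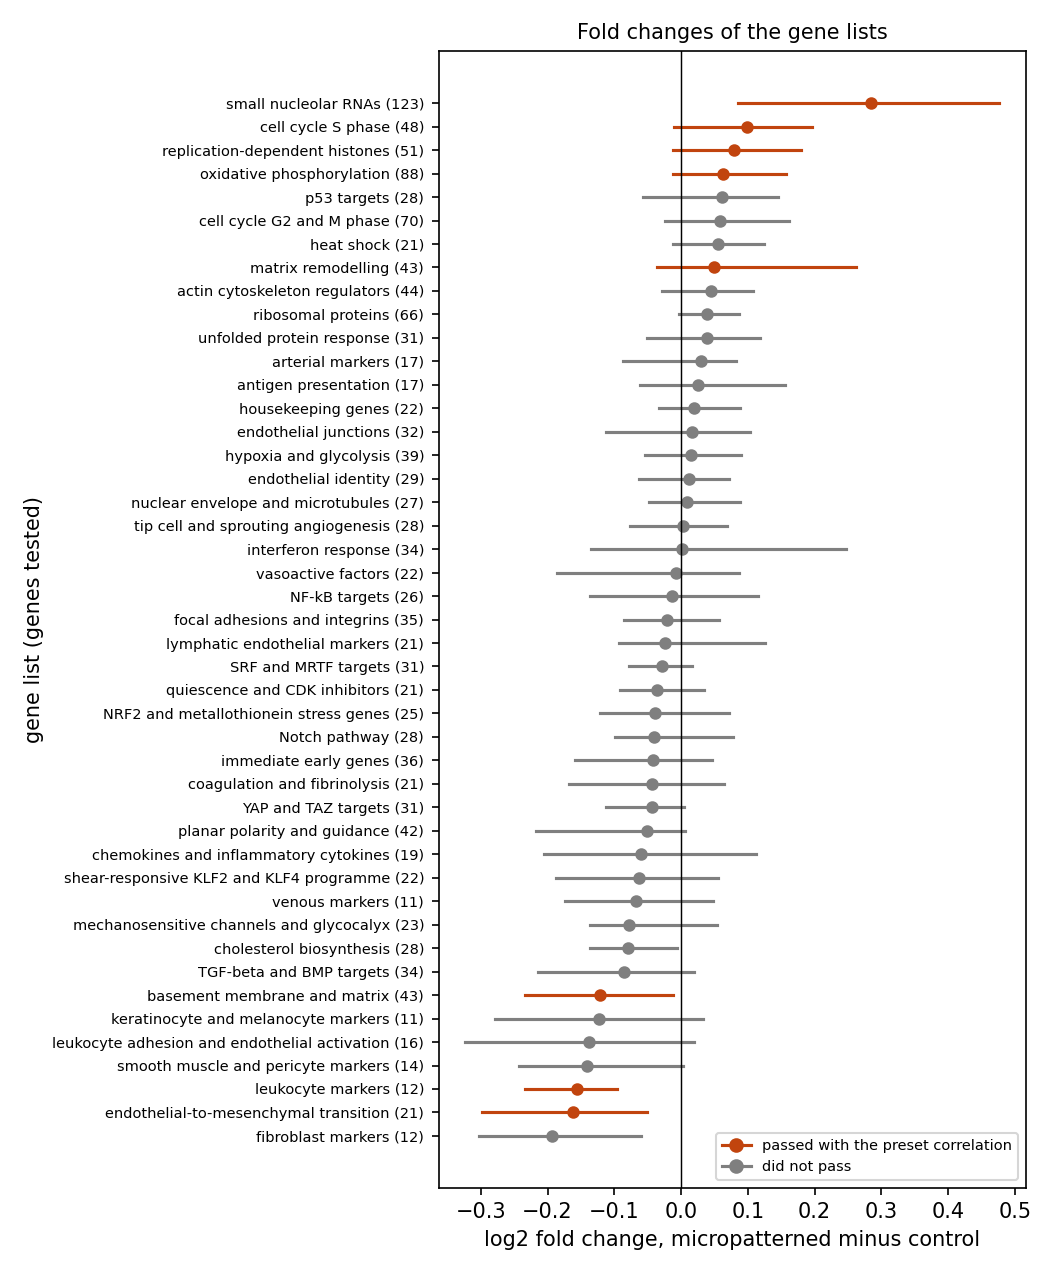
Median (point) and quartiles (line) of the members' log2 fold changes, micropatterned minus control, for each of the 45 gene lists, with the number of genes tested in brackets. The small nucleolar RNAs have the highest median, 0.28; the 8 lists in red passed with the preset correlation, and none of them passed with an estimated correlation.

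Of 45 gene lists, 8 moved apart from the other genes in limma's camera test with a preset correlation between genes, 5 higher and 3 lower on the channels. With an estimated correlation 0 lists passed, 1 list had an unadjusted p under 0.05, and each of the 8 had an adjusted p of 0.828. Camera with an estimated correlation has few degrees of freedom here, so a lost call does not measure the correlation alone. The oxidative phosphorylation list had an estimated correlation of -0.0074, below the preset 0.01. Its unadjusted camera p still went from 0.00139 with the preset to 0.0486 with the estimate. In limma's fry test 0 lists passed for a shift on balance in one direction, with 8 at an unadjusted p under 0.05. The mixed test, which asks for change in either direction, passed 36 lists. It does not compare a list with the other genes, and the housekeeping genes also passed it (fry mixed adjusted p = 0.00594). Passing it therefore does not set a list apart. Without micropatterned replicate 2, camera with the preset correlation passed 1 list. The median and mean of the lymphatic list differed in sign, -0.02 and 0.02.

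Some genes of the extracellular matrix were lower on the channels and some that remodel it were higher; both lists passed with the preset correlation, and had an adjusted p = 0.828 with an estimated correlation. Of 43 basement membrane and matrix genes, 5 fell, 0 rose and 38 did not pass (11 fell and 0 rose adjusted over the list alone). Elastin, ELN (probe set 8133372), had a log2 fold change of -0.70 ± 0.10 (adjusted p = 0.0269), the elastic fibre protein FBLN2 -0.45 ± 0.09, and the fibrillar collagen chains COL5A1 and COL1A1 -0.36 ± 0.08 and -0.35 ± 0.08. The list's median was -0.12 and turned to 0.03 with each array centred on its median; its camera adjusted p was 0.0208. It was 0.110 without micropatterned replicate 2, and from 0.00226 to 0.828 over 14 alternatives. Of 43 matrix remodelling genes, 4 rose and 0 fell (8 rose adjusted over the list alone). The collagenase MMP1 (probe set 7951271) rose by 0.68 ± 0.08 (adjusted p = 0.0246), the membrane-type metalloproteinase MMP16 by 0.64 ± 0.09, the cross-linking enzyme LOX by 0.47 ± 0.09 and the proteoglycan-cleaving ADAMTS9 by 0.42 ± 0.08. The list's median was 0.05, with a camera adjusted p of 0.0352. That adjusted p was 0.0638 after cyclic loess, 0.110 above the 50th percentile of signal and 0.0625 above the 75th, so the call was lost there. It was 0.173 without control replicate 2, 0.110 without micropatterned replicate 2, and from 0.0151 to 0.828 over 14 alternatives. Genes that belong to unrelated tissues were lower on the same arrays, among them 147 of 169 tested genes of hair, epidermis, smell, taste, defensin and MAGE families, grouped after the data were examined. The fibroblast markers, which share collagen genes with the matrix list, were lower in 11 of 12, with a median of -0.19, and did not pass (adjusted p = 0.0931).

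**Figure D2:**
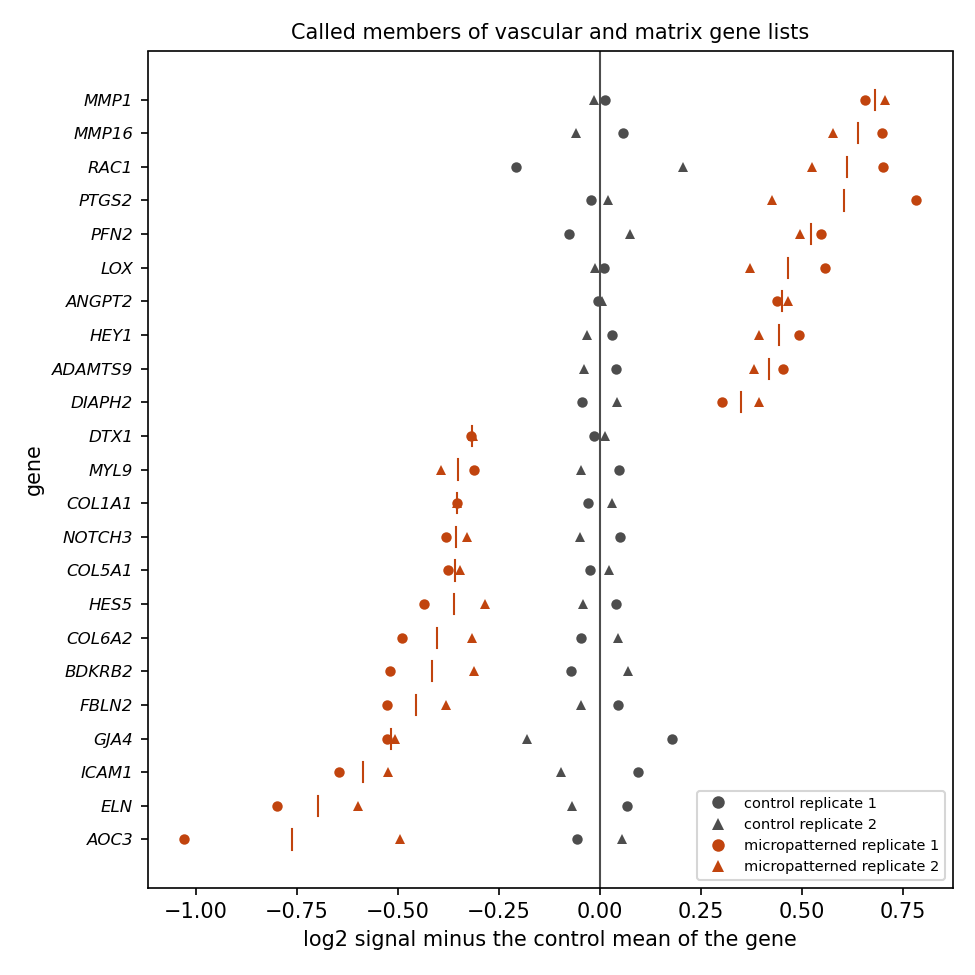
Log2 signal of each array minus the control mean of the gene, for the 23 genes that passed the test in 9 gene lists on matrix, adhesion, vessel signalling and cytoskeleton; circles are replicate 1, triangles replicate 2, grey control and red micropatterned, and short red bars the micropatterned mean. On the channels 10 of the genes were higher and 13 lower, and both micropatterned arrays lie on one side of both control arrays in each.

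ICAM1 and AOC3, which endothelial cells use to bind leukocytes, were lower on the channels. Of 16 leukocyte adhesion and activation genes, 2 fell and 14 did not pass (5 fell and 1 rose adjusted over the list alone). ICAM1 (probe set 8025601), an adhesion receptor for leukocyte integrins, had a log2 fold change of -0.58 ± 0.10 (adjusted p = 0.0281). The amine oxidase AOC3, also called vascular adhesion protein, had -0.76 ± 0.16, with -0.12 in its other probe set and -0.49 without micropatterned replicate 1. The list's median was -0.14, or 0.02 with each array centred on its median, and its camera adjusted p was 0.0878. It passed without the filter on dim probe sets (0.0435) and without micropatterned replicate 1 (0.0429), within a range of 0.0429 to 0.828 over 14 alternatives. None of 19 chemokine and cytokine genes passed in limma, with 6 at an unadjusted p under 0.05 and 0 adjusted over the list alone; CXCL2 had a log2 fold change of 0.35, CCL5 -0.41 and CXCL8 -0.39, or -0.25 without control replicate 2. This list passed, lower, among genes above the 75th percentile of signal (camera adjusted p = 0.0208, within a range to 0.828 over 14 alternatives). Among 26 NF-kB targets, ICAM1 fell and PTGS2, the inducible cyclooxygenase, rose by 0.61 ± 0.12 (2 rose and 2 fell adjusted over the list alone). Interferon-response genes went both ways: of 34, 1 rose and 2 fell (5 and 4 adjusted over the list alone), with IFIT2 at 0.49, OASL at -0.58 and ISG15 at -0.37. The micropatterned mean of OASL was 5.12, below the dim filter's log2 5.35. The interferon list passed, higher, without control replicate 2 (0.0273, within a range to 0.943 over 14 alternatives). In antigen presentation, 1 of 17 genes rose, the immunoproteasome subunit PSMB8 by 0.42 (1 rose adjusted over the list alone). The fixed list of leukocyte markers was also lower on these arrays, with a median of -0.16 (camera adjusted p = 0.0407, and 0.828 with an estimated correlation).

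Genes that define endothelial cells did not pass the test, but few genes as bright as these were called at all. The list's median level was log2 10.5, above the 75th percentile of signal, where 1.29% of tested genes were called. Over all 15065 tested genes, 4465 had an unadjusted p under 0.05 in limma. None of 29 endothelial identity genes was called by limma, with 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone; LYVE1 had 0.48 (adjusted p = 0.0928), or 0.27 without control replicate 2, and SOX17 had -0.26. VWF had -0.19, or -0.07 without control replicate 1 and -0.30 without control replicate 2. The vessel-destabilising ligand ANGPT2 (probe set 8149071) rose by 0.45 ± 0.08 (adjusted p = 0.0282), as 1 of 28 sprouting genes and 1 of 21 coagulation genes to pass (1 in each adjusted over the list alone). Of 28 Notch pathway genes, 1 rose and 3 fell (2 and 3 adjusted over the list alone): the target HEY1 was at 0.45 ± 0.09, the receptor NOTCH3 at -0.35 ± 0.08, the target HES5 at -0.36 and the ligase DTX1 at -0.32. Arterial markers held HEY1 and GJA4, the gap junction protein connexin 37, with 1 of 17 rising and 1 falling (2 and 1 adjusted over the list alone). GJA4 was at -0.52 ± 0.12, and -0.34 without control replicate 1; it was the single called gene of 32 junction genes (0 adjusted over the list alone, 7 at an unadjusted p under 0.05). Of 11 venous markers the ectonucleotidase ENTPD1 rose by 0.60 (1 rose and 2 fell adjusted over the list alone), and of 21 lymphatic markers TFF3 rose by 0.44 (0 adjusted over the list alone, 4 at an unadjusted p under 0.05). Among 22 vasoactive genes PTGS2 rose and the bradykinin receptor BDKRB2 fell by 0.41 (1 rose and 0 fell adjusted over the list alone). In the KLF2 and KLF4 programme, which flow induces, 0 of 22 passed in limma, with 5 at an unadjusted p under 0.05 and 0 adjusted over the list alone. That list's median level, 8.96, also lay above the 75th percentile of signal.

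Few genes of the machinery that senses and bears force passed. None of 31 YAP and TAZ targets was called by limma (5 at an unadjusted p under 0.05; AJUBA -0.29, adjusted p = 0.0572, or -0.09 with each array centred on its median), nor any of 35 focal adhesion and integrin genes (3 at an unadjusted p under 0.05; ITGA7 -0.30). None of 27 nuclear envelope and microtubule genes was called either (5 at an unadjusted p under 0.05; MAP1A -0.31, or -0.16 without micropatterned replicate 2). In each of these 3 lists the number adjusted over the list alone was also 0. Their median levels were log2 9.19, 10.2 and 10.2, above the 75th percentile of signal, where 1.29% of tested genes were called. So 0 calls do not set these 3 lists apart from other bright genes. The YAP and TAZ list had a camera adjusted p of 0.231; among genes above the 75th percentile of signal it was lower, with 0.00226, the lowest of 14 alternatives that ran to 0.858. Of 44 actin regulators, 3 rose (1 adjusted over the list alone): the small GTPase RAC1 by 0.61 ± 0.14, or 0.41 without control replicate 1, the actin monomer binder PFN2 by 0.52 ± 0.09 and the formin DIAPH2 by 0.35 ± 0.09. Of 31 SRF and MRTF targets, the myosin light chain MYL9 fell, at -0.35 ± 0.09 (0 adjusted over the list alone, 3 at an unadjusted p under 0.05); it was -0.17 and no longer called with each array centred on its median. Among 23 channel and glycocalyx genes, PKD1 was at -0.44 and the cation channel TRPC1 at 0.55 (1 fell and 1 rose, the same numbers adjusted over the list alone). The control mean of TRPC1 was 5.13, below the dim filter's log2 5.35. The planar polarity cadherins CELSR3 and CELSR2 fell by 0.43 and 0.46 among 42 polarity and guidance genes (1 fell adjusted over the list alone). That list had an adjusted p of 0.0878; it passed, lower, without control replicate 2 (0.0290) and without micropatterned replicate 1 (0.0429), within a range to 0.828 over 14 alternatives. Of 34 TGF-beta and BMP targets 2 fell (1 adjusted over the list alone), the activin antagonist FST by 0.53 ± 0.09 and HAMP by 0.32. That list had an adjusted p of 0.0878 and passed, lower, above the 50th percentile of signal (0.00833), above the 75th (0.000112) and with the trended and robust prior (0.0415), within a range to 0.828 over 14 alternatives. The list of 21 endothelial-to-mesenchymal transition genes had a median of -0.16 and lost its call with an estimated correlation (adjusted p = 0.828); 2 fell, COL1A1 and NOTCH3 (2 adjusted over the list alone). COL1A1 is also one of the fibroblast markers, of which 11 of 12 were lower (median -0.19), and NOTCH3 one of the smooth muscle and pericyte markers, of which 10 of 14 were lower (median -0.14); neither list passed. Its adjusted p was 0.0352, 0.118 without control replicate 2, 0.116 without micropatterned replicate 2, and from 0.0151 to 0.828 over 14 alternatives.

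Few genes of DNA replication passed, and both replication lists lost their call with an estimated correlation (adjusted p = 0.828 for each). Of 48 S phase genes 2 rose, the exonuclease EXO1 by 0.42 ± 0.09 and the replication factor GINS4 by 0.39 ± 0.09 (0 adjusted over the list alone, 5 at an unadjusted p under 0.05). The list's median was 0.10, 13 of the 48 genes were lower, and the adjusted p was 0.0352. It was 0.756 without control replicate 1 and 0.110 without micropatterned replicate 2, and ran from 2.9e-05 to 0.828 over 14 alternatives. Of 51 replication-dependent histone genes, which are close copies of one another and uncertain one by one, 2 rose, H2AC12 by 0.64 and H2BC11 by 0.32, or 0.19 with the values as deposited (1 rose adjusted over the list alone). That list had a median of 0.08 and an adjusted p of 0.0477. It was 0.0783 without control replicate 1, 0.0837 without control replicate 2 and 0.600 without micropatterned replicate 2, and ran from 0.000224 to 0.876 over 14 alternatives. None of 70 G2 and M phase genes was called by limma, with 8 at an unadjusted p under 0.05 and 0 adjusted over the list alone; SPC25 had 0.55 (adjusted p = 0.0637), or 0.29 without control replicate 1. The G2 and M phase list had a median level of log2 9.01, above the 75th percentile of signal, where 1.29% of tested genes were called. That list had a camera adjusted p of 0.231. It passed, higher, with the values as deposited (0.00879), with each array centred on its median (0.0111) and without control replicate 2 (2.9e-05), within a range to 0.943 over 14 alternatives. The cell cycle inhibitor CDKN1C was the 1 of 21 quiescence genes to fall, at -0.40 (0 adjusted over the list alone, 3 at an unadjusted p under 0.05), and it was -0.18 and not called with each array centred on its median.

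Some genes of mitochondrial respiration were higher; the list passed with the preset correlation and had an adjusted p = 0.828 with an estimated correlation. Of 88 oxidative phosphorylation genes 8 rose and 0 fell (7 adjusted over the list alone), among them the assembly factor NDUFAF1 by 0.56 ± 0.09, the complex III subunit UQCRH by 0.51 ± 0.11, and the complex I subunits NDUFB3 by 0.45 ± 0.10 and NDUFA5 by 0.43 ± 0.09. The list's median was 0.06, 28 of the 88 genes were lower, and the adjusted p was 0.0208. It was 0.116 without micropatterned replicate 2 and 0.0638 after cyclic loess, and ran from 0.000736 to 0.828 over 14 alternatives. In stress pathways few genes passed, some higher and some lower. Of 28 p53 targets, the pro-apoptotic BBC3 was at -0.70 ± 0.10 and the death receptors TNFRSF10A and FAS at 0.41 and 0.36 (1 fell and 2 rose, the same numbers adjusted over the list alone). Of 25 stress genes 3 fell (3 adjusted over the list alone), all from the metallothionein cluster: MT1H by 0.58, MT1F by 0.54 and MT1IP by 0.49, genes whose close sequences make their separate values uncertain. The heat shock relative HSPA4L rose by 0.55 as 1 of 21, DNAJB9 rose by 0.46 and DERL3 fell by 0.40 among 31 unfolded protein response genes, and the phosphatase DUSP2 fell by 0.50 and TRIB1 rose by 0.37 among 36 immediate early genes. These numbers were the same adjusted over the list alone. None of 39 hypoxia and glycolysis genes and none of 28 cholesterol genes was called by limma, with 4 and 3 at an unadjusted p under 0.05 and 0 in each adjusted over the list alone. Their median levels, log2 8.93 and 9.22, lay above the 75th percentile of signal, where 1.29% of tested genes were called. The cholesterol list passed, lower, among genes above the 75th percentile of signal (camera adjusted p = 0.000112, within a range to 0.893 over 14 alternatives). RPL22 rose by 0.62 as the 1 of 66 ribosomal protein genes to pass, and the transferrin receptor TFRC by 0.54 as 1 of 22 housekeeping genes (1 in each adjusted over the list alone).

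Small nucleolar RNAs, which guide the modification of ribosomal and spliceosomal RNA, had the highest median of the 45 lists. Of 123 tested, 28 rose, 1 fell and 94 did not pass (50 rose and 2 fell adjusted over the list alone), with a median of 0.28. SNORA5A rose by 0.76 ± 0.08 and SCARNA4 by 0.75 ± 0.08, the latter from a control mean of 5.31, below the dim filter's log2 5.35. The camera adjusted p was 1.3e-11, and 0.828 with an estimated correlation; it was 0.370 among genes above the 75th percentile of signal, and ran from 7.5e-15 to 0.828 over 14 alternatives. Most of these RNAs lie in introns of other genes, so signal from the host transcript cannot be excluded.

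Some markers of other cell types were lower on the channels, and 1 of 4 such lists passed. Of 12 leukocyte markers 11 were lower and 1 fell, NKG7, a cytotoxic granule protein, at -0.57 ± 0.12 (1 adjusted over the list alone); TYROBP had -0.44 (adjusted p = 0.0620), or -0.29 without control replicate 1. The list's adjusted p was 0.0407, and 0.828 with an estimated correlation. It was 0.0535 without control replicate 1, 0.0615 without control replicate 2 and 0.244 without micropatterned replicate 2, and ran from 0.00270 to 0.828 over 12 alternatives. Of 11 keratinocyte and melanocyte markers 2 fell (3 fell and 1 rose adjusted over the list alone), KRT16 at -0.77 ± 0.15 and KRT14 at -0.72 ± 0.16, the latter -0.47 without micropatterned replicate 1. KRT15 had 0.31 and KRT5 -0.28. Of 12 fibroblast markers LOX rose and COL1A1 fell (1 rose and 3 fell adjusted over the list alone), and of 14 smooth muscle and pericyte markers RGS5 rose by 0.53 and NOTCH3 fell (1 and 1 adjusted over the list alone). The last 3 lists did not pass, with adjusted p of 0.231, 0.0931 and 0.298. Keratinocyte and melanocyte markers passed, lower, with the values as deposited (0.0331) and with each array centred on its median (0.0282), within a range to 0.828 over 13 alternatives. Fibroblast markers passed, lower, under the same settings (0.0227 and 0.0173), without control replicate 1 (0.0495) and without micropatterned replicate 1 (0.0429), within a range to 0.828 over 13 alternatives.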

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

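Cyclic loess and the filter at the 75th percentile were chosen after seeing the data; a larger pseudocount was not run, since the values are already log2. Against 1542 genes called (698 higher, 844 lower), limma called 3094 with the values as deposited (1194 and 1900), 4308 with each array centred on its median (3201 and 1107), 5 above the 75th percentile (1 and 4) and 3097 at an adjusted p under 0.1 (1364 and 1733). Without the shared prior it called 0 (0 and 0), with 2416 at an unadjusted p under 0.05 and a smallest adjusted p of 0.139; that test has few degrees of freedom. Leaving out one array gave 0 to 1389 genes, 0 to 700 higher and 0 to 810 lower. Whether the numbers in the titles pair the samples is not known. Deviations of same-numbered arrays correlated at 0.0189 across genes, which cannot settle it, since it compares 1 difference per group. With a replicate block limma called 2011 genes (911 and 1100), and 8 lists passed. The 273 genes with no overlap became 139 above the 50th percentile and 20 above the 75th, where fewer genes are tested, and 208 to 620 with one array left out. Against 8 lists, 2 passed after cyclic loess (basement membrane and matrix, small nucleolar RNAs). Above the 50th percentile 4 passed, of which TGF-beta and BMP targets were not among the 8. Above the 75th percentile 5 passed, of which basement membrane and matrix was among the 8, and chemokines, YAP and TAZ targets, TGF-beta and BMP targets and cholesterol were not. The number was 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 1 to 11 with one array left out. With each array centred on its median LIMS2 turned from -0.18 to 0.0318 and FASN from -0.20 to 0.00799; neither passed in either setting, and centring raised the median of all genes to 0.15. Other than these shifts by construction, the cause was not tested. Of the 1542 genes, 1413 were also called with the values as deposited, 1383 after median centring, 1289 after cyclic loess, 1326 with the trended and robust prior and 1106 without the filter, and all 1542 had the same sign under these settings. With the mean over a gene's probe sets 1538 of them were tested, 1513 were called and 1534 had the same sign. Signal over background is not known for these values, which limits what can be said of dim genes.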

Other observations

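The array-wide test, the keratinocyte test, the families' medians within the pairs, the test of middle signal and all 9 gene families were chosen after the result was seen, as were cyclic loess and the 75th percentile filter. Some families of genes with similar sequences were shifted in one direction. Of 424 tested C2H2 zinc finger genes, 327 were higher on the channels (77.1%), 88 rose and 9 fell, with a median log2 fold change of 0.20, which was 0.17 with the values as deposited, 0.28 after median centring and 0.22 after cyclic loess. All 12 tested clustered beta protocadherins were higher, with a median of 0.25 and 2 that rose, while all 6 tested alpha and gamma protocadherins were lower, with a median of -0.28 and 2 that fell; both medians kept their sign under the 3 other scalings, which was not checked for single members. Camera gave an unadjusted p of 1.0e-11 for the zinc finger genes and 0.0549 with an estimated correlation. Beta protocadherins gave 0.000554 and 0.0941, and alpha and gamma protocadherins 0.0102 and 0.119. Close sequences make single members of these families uncertain.

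Genes of families that belong to other tissues were mostly lower on the channels. Of 48 keratin-associated proteins 45 were lower, with a median of -0.40 and 24 that fell; of 21 late cornified envelope and small proline-rich genes 20 were lower, with a median of -0.40 and 10 that fell; and of 76 olfactory receptors 65 were lower, with a median of -0.24 and 15 that fell. Beta-defensins were lower in 4 of 4 and MAGE genes in 7 of 8. Taste receptors were lower in 6 of 12, with 3 that rose and 1 that fell, against 3 and 53 in all 6 families. Their median of 0.00 was -0.11 with the values as deposited and 0.04 after cyclic loess. Camera with an estimated correlation gave the 6 families together an unadjusted p of 0.0733. Probe sets with several gene symbols or none, were fitted apart: limma called 0 of 6994, with 1671 at an unadjusted p under 0.05 and a smallest adjusted p of 0.110.

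For the lower signal of families of other tissues, the quantile normalization used here is argued against. The median of the 6 families was -0.37 with the values as deposited and -0.24 after cyclic loess. Any normalization made before deposit is not given, so these values cannot test it and it stays open. Keratinocytes in the control cultures stay open. The olfactory receptors, which keratinocytes do not need, had a median of -0.24, which keratinocytes alone would not give. They cannot decide it, since they are 76 of the 169 genes of the pattern and the test was chosen afterwards. Their median level was also log2 5.75, near the dim filter's 5.35. The keratinocyte genes KRT14 and KRT16 fell, at -0.72 and -0.77 from control means of 7.92 and 7.65, levels that decide nothing by themselves. KRT5 had -0.28 from a control mean of 6.16 and KRT15 0.31 from 6.13, and neither passed. Of the 11 keratinocyte and melanocyte markers, 7 were lower and 4 higher. A difference between the array pairs in RNA, labelling or hybridization stays open: the 87.0% of genes that were lower restates the pattern, and the taste receptors, at 50% (exact 95% interval 21.1% to 78.9%), are too few to exclude the 70% it needs. A difference that also runs within the groups stays open too: the families' median was -0.0859 for micropatterned replicate 1 minus 2 and -0.050 for control replicate 2 minus 1, against -0.29 between the groups, while over the 45 lists the median fold change correlated at r = 0.00608 with the micropatterned pair and 0.396 with the control pair. Across genes, which are not independent replicates, the fold change correlated at 0.378 with micropatterned replicate 1 minus 2 and 0.259 with control replicate 2 minus 1; unequal noise of the arrays would also give such values, so they decide nothing.

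For the adhesion and matrix genes that fell, the same array-wide difference cannot be told apart from a response to the channels. Of the 7 called members, 1 lay below the 5% bound of the families' fold changes (-0.71), namely AOC3 at -0.76, and the other 6, from ELN at -0.70 to COL1A1 at -0.35, lay within the families' range. What keeps it open is that each group is 1 pair of arrays. A biological effect of the surface stays open and was not tested apart from the array pair.

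The share of genes called was 7.94 times as high over all tested genes as above the 75th percentile of signal (10.2% against 1.29%). A drop of over 5 times was set before the result was seen as what a difference mostly among dim probe sets needs, so that test came out for the explanation, whose wording was changed afterwards. It does not separate dim from middle signal. The test added later came out the other way: the share called from the 50th to the 75th percentile was 1.04 times that below the 50th (15.7% and 15.1%). It cannot decide the question, since genes of other tissues also lie at middle signal. Keratin-associated proteins had a median level of log2 7.02 and the cornified envelope and small proline-rich genes 7.16, against array medians of 6.62 to 6.73. The explanation stays open. Why calls were rare above the 75th percentile was not tested.

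When genes above the 75th percentile were tested alone, 5 passed: MMP1 at 0.68, and ZBTB22 (-1.21), KRTAP10-4 (-0.82), FAM201B (-0.78) and LINC00937 (-0.63). FAM201B and LINC00937 were named after their values were seen. The basement membrane and matrix list kept its lower direction there, with an adjusted p of 0.00226 among 14 alternatives that ran from 0.00226 to 0.828.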
